A study of Mus musculus with 6 samples.

How the data were processed

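DNase I hypersensitive sites were measured in the livers of C57BL/6 mice, with 3 fed and 3 fasted samples. Per the labels' protocols, nuclei from fresh liver were treated with DNase I at 40 U/ml, and fragments of 100 to 500 bp were purified on a sucrose gradient. The submitters' processing notes name CASAVA 1.8 and the genome build mm9. The aligner and the hotspot caller are not given in the sources used here. Each library has its own list, so hotspots were called per sample and not on pooled samples.

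Per the file headers, each hotspot has a position, a maximum and an average density, a z-score and a p-value. The maximum and average tag density deposited by the authors are a coverage signal, whose scale is not given in the sources used here. The z-score is the authors' own score for each hotspot and was used for no comparison. The p-value deposited by the authors was at most 4.5e-13 in any library, and it was used for no comparison either. The lists hold only called hotspots, so a region missing from a list has an unknown density. Coordinates are given as in the files. Of 329482 hotspots, 0 passed the end of an mm9 chromosome and 2515 passed the end of an mm10 chromosome (chromosome lengths from GenomeInfoDb 1.38.1).

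Hotspots that overlapped by at least 1 bp in any of the 6 lists on chromosomes 1 to 19 and X were merged into union regions, and a library called a region when one of its hotspots lay in it. The density of a region in a library is the highest maximum tag density of its hotspots there. Group comparisons of list sizes, covered length and pairwise overlap used exact permutation tests, which cannot go below p = 0.1 for 3 against 3. Regions called in 1 group only were counted. Regions called in all 6 libraries were tested with limma 3.58.1 (R 4.3.3; eBayes with a mean-variance trend) on log2(density + 1), with each library centred on its median over these regions and Benjamini-Hochberg adjustment (threshold 0.05). No count model was used, since the values are heights of overlapping tags and not counts per region. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

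Relative depth came from the step of the maximum tag densities, since every maximum was a whole multiple of it (100% within 0.05 step). This assumes that 1 step is 1 tag and that each library was scaled to its total of tags. The 5th percentile of hotspot height was 13 to 16 tags, so weak hotspots carry a large counting error. The heights of replicates of 1 group differed by more than sampling noise (mean squared z of 2.18 to 5.73, where 1.0 would be sampling noise alone), so no library was counted as a duplicate.

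The limma step was tested on simulated data for fasted against fed, with 200 of 37044 regions changed. It recovered 94% of regions raised by 1 on the log2 scale, 72% of those lowered by 1, 12% of those raised by 0.5 and 14% of those lowered by 0.5, and called 4 unchanged regions. With none changed it called 0. Fewer regions changed there than passed in the data, so the adjusted threshold was stricter, which may understate recovery in the real fit. Every region and library had the same added spread and no region was lost for a missing call, unlike in the data. That may overstate recovery and understate false calls, so the direction of the difference is unknown.

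The named regions follow a rule set before the data were examined, as were the main tests and most alternatives. In each direction they are the 10 regions with the largest absolute log2 fold change among those past the threshold whose groups do not overlap, and the 10 regions called in 1 group only with the highest mean density. Regions on chromosome 8 near these were drawn after their values were seen. The alternatives were other pseudocounts (0.1 and 10), no centring, quantile normalization, average density, missing values at the lowest density of the library, only the upper 50% of regions by density, the variance model, the replicate number as a block, hotspots covering at least 50% of a region, merging within 150 bp, stricter and equal-length lists, and leaving out each replicate. Depth as a covariate and regions with exactly 1 hotspot of each library were added after the data were seen. The named shared regions were picked on the main fit, so refits of the same data could hardly lose them. Not all were in every fit. Absent from the upper 50% were chromosome 18 at 54409327 and chromosome 16 at 48811547. Chromosome 18 at 54409327, chromosome 8 at 112518303 and chromosome 11 at 76521282 were absent from the fit with 1 hotspot of each library. So were chromosome 13 at 16407238 and chromosome 1 at 83896494. An exploratory limma fit, with all 10 splits of the libraries into 3 and 3, was looked at before the tests of technical explanations were written down.

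Hotspots on chromosome Y were left out of the comparisons. Gene names, distances to start sites, gene lists and motif searches were planned, but no annotation or sequence of mm9 was used here, so regions are named by coordinates only. Coordinates were not converted to another build.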

Results

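DNase I hypersensitive sites were mapped by sequencing in livers of C57BL/6 mice, an inbred laboratory strain. DNase I cuts DNA where chromatin is open, so a local excess of sequenced ends (a hotspot) marks accessible DNA such as promoters and enhancers. The series held 6 libraries, 3 from mice fed ad libitum and 3 from mice fasted for 24 h, and the comparison asked which accessible regions of the liver differ after fasting. The labels give replicate numbers but do not say that each came from a separate animal, so p-values measure the spread between these samples, which may be partly technical. The fed libraries held 51609, 50990 and 63105 hotspots, and the fasted libraries 49682, 63476 and 50620. Within each library the maximum tag densities were whole multiples of a single step (100% of values within 0.05 step). The step gives relative depth if 1 step is 1 tag and each library was scaled to its total of tags. The sources used here do not state this. Fed replicate 3 and fasted replicate 2 were the deepest, at 1.64 and 1.90 times the depth of fed replicate 2, the shallowest. The others stood at 1.02 (fed replicate 1), 1.32 (fasted replicate 1) and 1.24 times (fasted replicate 3). The median hotspot reached a height of 44 to 57 tags across the 6 libraries.

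The number of hotspots and the length of DNA they covered varied more between replicates than between fed and fasted livers. On chromosomes 1 to 19 and X the hotspots numbered 55145 ± 6819 (SD, n = 3) in fed and 54499 ± 7695 (SD, n = 3) in fasted libraries. They covered 46.3 ± 8.19 Mb in fed and 46.7 ± 7.80 Mb in fasted libraries. Neither difference exceeded the spread between replicates (two-sided exact permutation p = 0.6 for both, smallest possible p = 0.1). The sign of the number difference, -645.7 hotspots, turned without fed replicate 3 (3287.5), fasted replicate 1 (1806) or fasted replicate 3 (1337), and the difference was -2377 at a single density threshold for all libraries (exact permutation p = 0.2). The sign of the covered length difference, 0.42 Mb, turned without fed replicate 1 (-2.15 Mb), fed replicate 2 (-1.73 Mb) or fasted replicate 2 (-4.08 Mb), and at that threshold (-1.26 Mb).

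Hotspot lists and densities were on average less alike between fed and fasted livers than within a group. The Jaccard index, the bases shared by a pair of lists over the bases in either, was 0.729 ± 0.044 (SD) over the 6 pairs of libraries of the same group. It was 0.693 ± 0.035 (SD) over the 9 pairs of a fed and a fasted library, a difference of 0.0363 (one-sided exact permutation p = 0.1 over 10 splits, the smallest possible). The ranges overlapped, from 0.695 to 0.805 within and 0.636 to 0.730 between groups. Fed replicate 3 and fasted replicate 2, the deepest libraries, stood at 0.712, inside the range of pairs within a group. Merging the 6 lists gave 75169 regions (67.6 Mb). Of these, 37044 (49.3%) were called in all 6 libraries, with a median width of 1054 bp and a median density of 23.7. Over these shared regions the log2 densities of libraries of 1 group correlated at 0.943 to 0.969, and those of a fed and a fasted library at 0.882 to 0.912. These correlations are across regions, which are not independent replicates. The first principal component, with 54.9% of the variance, separated the groups, and on the second (16.6%) fasted replicate 2 lay apart at -46.5 while fasted replicate 3 lay at 32.5.

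**Figure D1:**
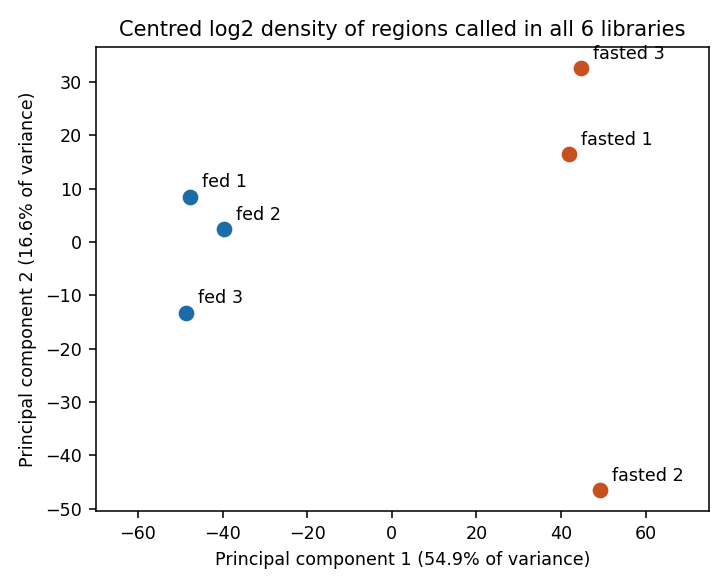
Each point is a library, placed by the first 2 principal components (arbitrary units) of the centred log2 densities of the 37044 regions called in all 6 libraries. Fed libraries (blue) lie between -48.7 and -39.7 and fasted libraries (orange) between 42.0 and 49.3 on the first component.

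Fasting went with a gain of density at 2921 of the 37044 shared regions and a loss at 2905, together 15.7% (limma, Benjamini-Hochberg adjusted p under 0.05). The median log2 fold change, fasted minus fed, was 0.78 among the regions that rose and -0.87 among those that fell. Among the risen regions 730 changed by at least 1 on the log2 scale and 24 by at least 2, and among the fallen regions 1079 and 100 did. Fold changes are on the log2(density + 1) scale after each library was centred on its median over the shared regions, and understate the change of weak regions. The groups did not overlap at 31.4% of the shared regions, against 10% by chance for 3 against 3. The balance of gains and losses depended on the centring: 50.1% of the changed regions rose with it, and 37.9% (1946 rose and 3189 fell) with densities as deposited, where the median over all shared regions was -0.04 in place of 0.03. Without fasted replicate 1 the number that rose was 1911.

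**Figure D2:**
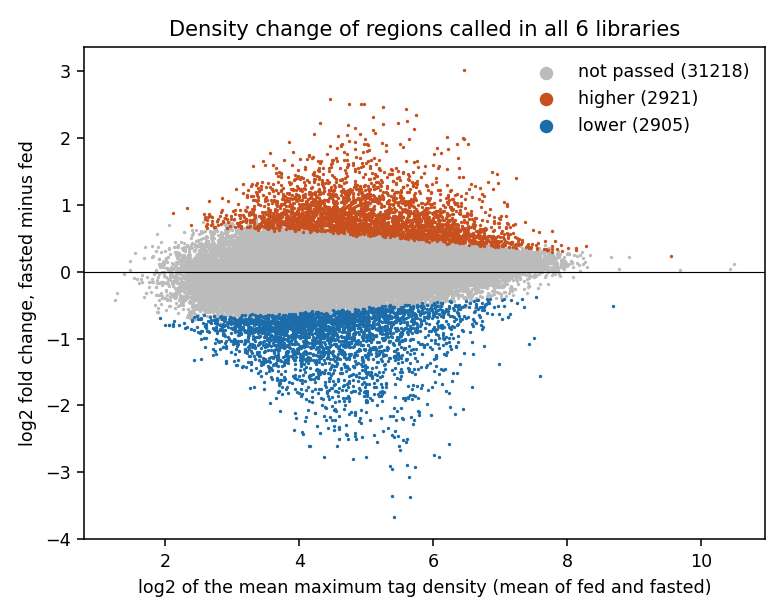
Each point is 1 of the 37044 shared regions, with the log2 of its mean maximum tag density on the horizontal axis and its log2 fold change, fasted minus fed, on the vertical axis. Orange points (2921) were higher and blue points (2905) lower in fasted livers at an adjusted p under 0.05 (limma), and grey points did not pass.

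The region that rose most lies on chromosome 18 (mm9, 11143932 to 11145530), where the maximum tag density went from 20.2 ± 8.16 in fed to 156 ± 17.2 in fasted livers (SD, n = 3 each). Its log2 fold change was 3.02 (SE 0.21, adjusted p = 1.2e-08, limma). A second region of chromosome 18 (54409327 to 54411059) went from 6.29 ± 3.48 to 37.5 ± 4.62, a log2 fold change of 2.58. Regions of chromosome 16 (18712866 to 18713932) and chromosome 10 (68566780 to 68568079) rose by 2.51 and 2.50 on the log2 scale, the latter from 9.05 ± 1.10 to 53.2 ± 6.39. A region of chromosome 15 (25874468 to 25875651) also rose by 2.50, with fasted libraries from 28.2 to 68.5. Both regions of chromosome 8 among the 10 with the greatest rise lie 6.00 kb apart: 112511344 to 112512303 went from 11.4 ± 2.50 to 64.5 ± 15.4, and 112518303 to 112525608 from 15.7 ± 6.09 to 81.4 ± 15.0. The other 3 lie on chromosome 3 (96375228 to 96376477) and on chromosome 11 (76521282 to 76524220 and 11744103 to 11745705), with log2 fold changes of 2.34, 2.31 and 2.26. In all 10 the lowest fasted library stood above the highest fed one, which the naming rule required on centred densities.

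**Figure D3:**
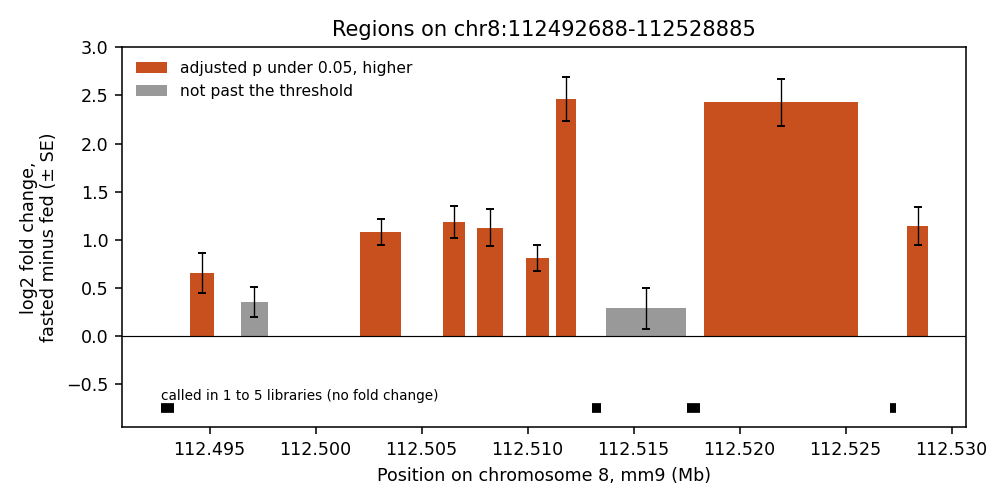
Bars show the log2 fold change, fasted minus fed, of the regions of chromosome 8 (mm9, position in Mb) called in all 6 libraries, drawn at their width, with error bars of 1 SE. In this stretch 8 regions rose (orange), with changes from 0.65 to 2.46, 2 did not pass the test (grey, 0.35 and 0.29), and black marks show regions called in fewer libraries.

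Among the regions that fell, a region of chromosome 14 (11582371 to 11584068) had the greatest loss, from 80.2 ± 28.0 in fed to 4.80 ± 0.057 in fasted livers (SD, n = 3 each), a log2 fold change of -3.67 (SE 0.24, adjusted p = 5.9e-09, limma). On chromosome 13 (46248402 to 46249373) the density fell from 93.0 ± 22.4 to 7.51 ± 1.41 (log2 fold change -3.37), and on chromosome 11 (16488684 to 16490069) from 76.8 ± 11.9 to 6.50 ± 2.75 (-3.35). On chromosome 4 (130272089 to 130273206) it fell from 90.4 ± 19.2 to 9.26 ± 1.31 (-3.07). The next were regions of chromosome 6 (24157330 to 24158641, log2 fold change -2.96), chromosome 13 (16407238 to 16409324, -2.93), chromosome 6 (139919836 to 139921024, -2.90) and chromosome 4 (62384548 to 62385629, -2.89). Regions of chromosome 1 (83896494 to 83898170, -2.80) and chromosome 16 (48811547 to 48812738, -2.78) completed the 10. Each had a hotspot call in every fasted library, as all tested regions must, at densities of 3.55 to 18.2.

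**Figure D4:**
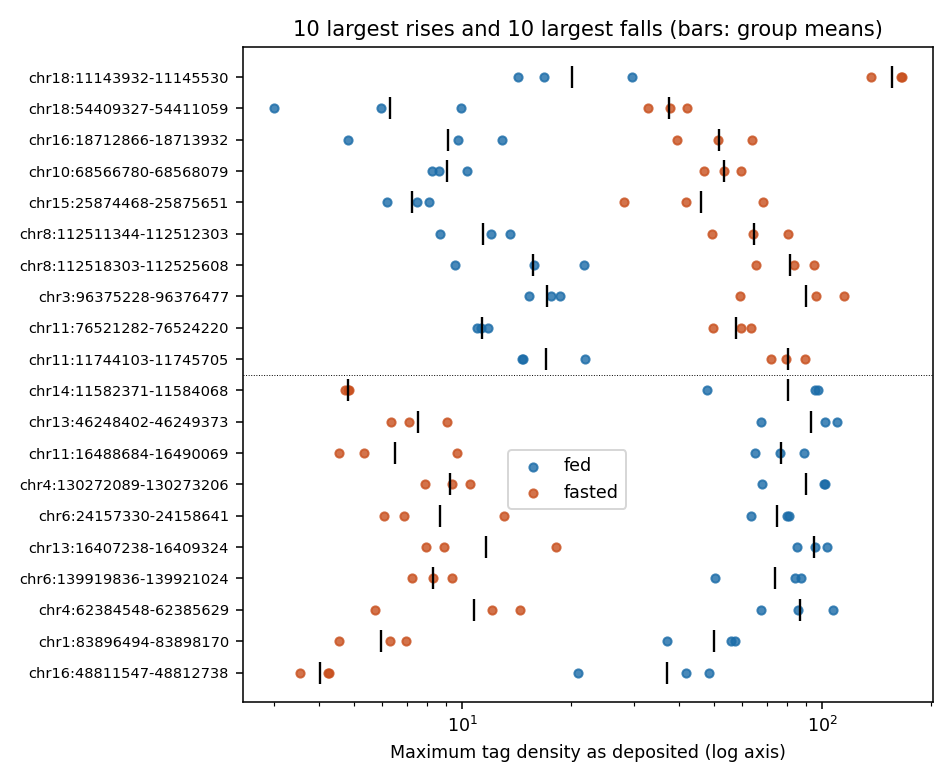
Each row is 1 of the 10 regions with the greatest rise (above the dotted line) or fall (below it), each point a library (fed blue, fasted orange) and each black bar a group mean, on a log axis of the maximum tag density as deposited. In every row the 3 fed and the 3 fasted libraries do not overlap, which the naming rule required on centred densities.

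Some sites were called in a single group. In all 3 fasted and no fed libraries 879 regions were called (1.17% of 75169), and in all 3 fed and no fasted libraries 1183 (1.57%). Most were weak, with a median density of 8.78 for the fasted set and 11.01 for the fed set against 23.7 for shared regions. The strongest of the fasted set lies on chromosome 17 (31994743 to 31995653), at a density of 66.7 ± 14.1 (SD, n = 3), followed by chromosome 5 (136115595 to 136116965) at 49.3 ± 14.9 and chromosome 2 (160630607 to 160631507) at 42.6 ± 4.65. The chromosome 2 region joined fed-called neighbours when hotspots within 150 bp were merged. On chromosome 3 a pair of the 10 strongest (96363598 to 96366799 and 96367083 to 96368490, densities 32.6 ± 17.2 and 32.96 ± 13.9) lies 6.74 kb or more from the risen region at 96375228. Strongest in the fed set were regions of chromosome 9 (74638880 to 74639859) at 82.5 ± 15.7 and chromosome 6 (121120793 to 121121850) at 80.4 ± 5.48. A region of chromosome 7 (4766593 to 4767792) at 75.8 ± 24.9 came next, then a pair 2.64 kb apart on chromosome 12 (105230197 to 105231744 and 105234386 to 105235315) at 72.3 ± 16.3 and 69.2 ± 6.83. On chromosome 1 a site of the fasted set (40189406 to 40190527, 41.9 ± 19.8) and one of the fed set (40293321 to 40294304, 63.5 ± 17.7) lay 103 kb apart.

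A missing call is not a density of 0, and the number of sites called in a single group depended on the lists. With every list shortened to its 49595 strongest hotspots, 1024 regions were called in fasted and 1233 in fed livers only. The fasted set grew to 2024 without fed replicate 3, 1566 without fasted replicate 1 and 1447 without fasted replicate 3, and the fed set to 1940, 2406 and 2285 without fed replicate 1, fed replicate 2 and fasted replicate 2. Of the regions called in 1 library only, 14627 in all, 80.4% came from fed replicate 3 and fasted replicate 2.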

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

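Hotspots on chromosome Y lay outside the comparisons, which used chromosomes 1 to 19 and X, and were looked at after the data were seen. Every library had them, which is a signal in data that the comparisons did not use. There were 88, 88 and 94 in fed replicates 1 to 3 and 87, 108 and 86 in fasted replicates 1 to 3. Their median maximum tag density was 15.6, 13.9 and 12.8 in the fed and 13.3, 12.0 and 15.0 in the fasted libraries. Medians on the autosomes were 18.02, 16.9 and 12.4 in the fed and 16.5, 10.5 and 17.0 in the fasted libraries, and those on the X chromosome 9.93, 8.99 and 6.52 in the fed and 8.51, 5.33 and 9.38 in the fasted libraries. No explanation was tested for these values.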

How the results depend on the processing

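Depth as a covariate and regions with 1 hotspot of each library were chosen after the data were seen. Under the 18 alternatives to the limma fit, 0 regions that had changed passed in the opposite direction. The 2921 regions higher in fasted livers became 1946 with no centring, and 1401 (lower: 1540 in place of 2905) in the upper 50% of regions by density, where fewer regions were tested. Leaving out each replicate gave 1911 (without fasted replicate 1) to 3199 higher and 2048 to 2698 lower regions. The remaining settings gave 2468 to 3185 higher and 2539 to 3599 lower regions, the most with missing values at the lowest density of the library, which fixes the direction of regions called in 1 group only. That setting kept 2050 of the 2921 higher and 1912 of the 2905 lower regions (68.0%). Same-numbered libraries did not deviate together (correlations of -0.067, -0.030 and -0.167). This gave no sign of pairing by number, but deviations from means of 3 libraries cannot rule it out. The replicate block gave 2535 higher and 2539 lower regions. For the 20 named shared regions, picked for large changes, 353 of 353 available values kept direction and passed. For the 20 named regions called in 1 group only, 79 of 80 values stayed the same. Only merging within 150 bp tested for calls of the other group, since the other rules can only drop calls. There chromosome 2 at 160630607 joined fed-called neighbours and lost its call.

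Without each replicate in turn, 1017 to 2024 regions were called in fasted livers only and 1327 to 2406 in fed livers only, since fewer libraries must agree. Other rules gave 597 to 1050 and 848 to 1377. The overlap difference stayed between 0.0253 and 0.0484, but without fed replicate 1, fed replicate 2, fasted replicate 1 or fasted replicate 3 another split was as large (exact permutation p = 0.2). The hotspot number difference ran from -5080 to 3287.5 on leaving out each replicate (reversed without fed replicate 3, 3287.5; fasted replicate 1, 1806; fasted replicate 3, 1337) and was -2377 at a single density threshold (exact permutation p = 0.2). The covered length difference ran from -4.08 to 5.14 Mb (reversed without fed replicate 1, -2.15; fed replicate 2, -1.73; fasted replicate 2, -4.08) and was -1.26 Mb at that threshold; the cause was not tested. Distances to start sites, gene list units and motif settings were not run, since their results were not made. With the simulated spread and 3 libraries per group, a change of 0.5 on the log2 scale was found in 12% (raised) and 14% (lowered) of regions. Only 200 of 37044 simulated regions changed, against 5826 that passed in the data, so the adjusted threshold was stricter. These shares do not measure the sensitivity of the real fit, and how far depth set these simulated shares was not tested.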

Other observations

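The neighbour, stretch, density quartile and chromosome analyses were chosen after the data were seen. The neighbours and stretches were analysed with 1 set of distances, and the quartiles were also counted under several of the other limma settings. The tests of the splits by density and of depth as a covariate were written after their results had been seen, and the tests on lists of equal number after the counts for fed against fasted livers were known but before those of the other splits.

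Accessible regions changed together with their neighbours. The correlation of log2 fold changes between shared regions was 0.427 when they lay under 1 kb apart, 0.403 at 1 to 5 kb, 0.274 at 5 to 20 kb, 0.124 at 20 to 100 kb and 0.032 at 100 to 500 kb. Among pairs 5 to 20 kb apart in which both regions changed, 938 of 1098 (85.4%) changed in the same direction. Counting shared regions that changed and regions called in 1 group only, 100 stretches held 4 or more risen regions with gaps of at most 20 kb, 499 regions in all. After 1000 shuffles of the calls within density quartiles the mean was 5.05 stretches and the highest 14. There were 57 stretches of fallen regions (252 regions), against a shuffled mean of 4.73 and a highest of 13. Both permutation p-values were 0.001, the smallest that 1000 shuffles can give. Their units are regions, so they measure placement along the genome and not the spread between samples.

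The largest risen stretch lies on chromosome 12 (mm9, 85322397 to 85410591), where 12 regions rose, 2 did not pass and none fell, with a median log2 fold change of 1.02 over the 10 shared ones. Stretches of 11 risen regions on chromosome 15 (88657944 to 88753025, with 1 fallen region inside), 10 on chromosome 13 (94384169 to 94424106) and 10 on chromosome 19 (46702542 to 46782652) followed. The largest stretch in any shuffle held 8 regions in either direction. The largest fallen stretch held 7 regions, on chromosome 9 (74166352 to 74180839, median log2 fold change -1.11), so its size does not exceed the shuffles, and 2 on chromosome 13 held 6 (46112995 to 46152135, -0.88, and 113072461 to 113145103, -0.65).

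A candidate explanation for neighbours changing together is a single broad open site split into several regions. The bound written before this test was a correlation under 0.05 at 5 to 20 kb, and the correlation there was 0.274. This argues against split sites that end within 5 kb as the only source, but it cannot speak to pairs under 5 kb. Split sites may add to the higher correlations there and to the stretches, which also counted regions with small gaps. A broader open domain could give a correlation at 5 to 20 kb and was not tested. Regional bias of single libraries would also appear between libraries of 1 group, yet the covariance of neighbours there was 8.22% of that of the fasting contrast at 5 to 20 kb. Fasting acting on neighbouring sites of a locus together also stays open, as a hypothesis found and tested on the same data. So do regional properties such as base content, which were not tested without a genome sequence. Anything else that differed between the groups, such as the extent of digestion, could also shift neighbours together and was not tested.

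In 1 of the 10 splits into 3 and 3, fed against fasted itself, were as many regions higher (2921) or lower (2905), and the highest of the other splits gave 0 in limma, with 483 to 1686 regions at an unadjusted p under 0.05 against 10243. Every other split has fed and fasted libraries on both sides, so the fasting difference enters its spread and few calls can be made: all lie below the 1852 that chance alone would give. With 10 splits a share under 0.05 cannot be reached. Depth as the whole cause, with depth inferred from the density step, is argued against by the fit with it as a covariate. There 82.0% of the changed regions kept their call and direction. A different enrichment of each library as the whole cause is argued against by quantile normalization, under which 85.8% of the changed regions kept their call and direction. It could still have a part in the calls, since the uneven spread of rises and falls over density, given below, narrowed under that normalization. A change in the mix of liver cell types, the extent of digestion and the day of preparation stay open beside fasting, and none of them was tested.

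In the lists as deposited, 2 of the 10 splits gave at least the 879 regions of fasted livers only and 1 gave the 1183 of fed livers only, and the highest other split, fed replicates 1 and 3 with fasted replicate 2 against the rest, gave 880. That split joins the deepest libraries, as do those with 692, 748 and 773, and the other splits that part them, as fed against fasted does, gave 94 to 114. With lists of equal number 1 of 10 splits gave as many as the 1024 and 1 of 10 as many as the 1233, and the highest other split gave 344, again with a share that cannot go under 0.05. The splits with both deepest libraries together still gave 216 to 344 there, and the other mixed splits 94 to 115, so list length alone does not account for the difference. Shortening the lists also took the share of the 2 deepest libraries among regions called in 1 library only from 80.4% to 47.2%, between the bounds set beforehand (45 and 55), so depth and other properties of those libraries cannot be told apart for these regions.

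Rises and falls were spread unevenly over density. In the weakest quartile of shared regions 3.35% rose and 8.07% fell, and in the strongest 10.1% rose and 3.88% fell. With quantile normalization the gap narrowed, to 436 risen and 546 fallen regions in the weakest and 563 and 512 in the strongest quartile. With densities as deposited the counts were 204 and 871 in the weakest and 536 and 377 in the strongest.

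No chromosome stood apart after correction for 40 tests (lowest adjusted p = 0.45, permutation test by rotating the calls along the genome). The X chromosome had the lowest raw p (0.015), with 6.02% of its regions risen against 9.72% of all.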
